A study of Mus musculus with 4 samples.

How the data were processed

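Total RNA of mouse melan-a melanocyte cultures was measured on 4 Affymetrix expression arrays, 1 per condition. Per the labels, cells were starved in medium with dialyzed serum, and 3 of the 4 cultures also received 100 ng/ml EGF for 14 days. The 4 conditions were Hmhi cells starved, Hmhi cells with EGF, Hmhi-Miz1 kd cells with EGF and Hmhi-MYC-TA cells with EGF. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA with the IVT-Express kit. The labels do not spell out Hmhi or MYC-TA.

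The deposited values were taken as log2 signals, from their range of 2.94 to 15.12 over 45101 probe sets. The sorted values of the 4 columns lay within 0.004 of each other, so the authors' values had already been made comparable between arrays. The labels state neither the log base nor the methods of summarization and normalization. Near-identical sorted columns are what quantile normalization gives, so the equal medians are imposed and a shift of all genes cannot be seen. The log base and the summarization stay unknown. The values were not centred per gene, and every difference below runs from the second array named to the first. Each column's median was 6.66.

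The platform annotation of 2016 gave 1 gene symbol for 34945 probe sets and several for 932. It named no gene for 9160 other non-control sets, which are unnamed here, and 64 were control sets. Entrez identifiers matched the RefSeq gene table for 34754 probe sets, and the update changed 0 symbols. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays, which was a choice among several sets for 9010 genes. A gene entered a comparison if the brighter of its arrays was at or above that array's median of non-control sets.

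With 1 array per condition there was no residual spread, so no test was run and no p-value is given. The comparisons were Hmhi EGF minus Hmhi starved, Miz1 kd EGF minus Hmhi EGF, MYC-TA EGF minus Hmhi EGF, and MYC-TA EGF minus Miz1 kd EGF. Genes at least 2-fold apart were counted. The only error available was technical, the SD between probe sets of a gene within a comparison. It was 0.32, 0.22, 0.25 and 0.40 on the log2 scale for the 4 comparisons in that order. The small number of arrays limits the precision of every value.

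The median difference of each of 22 gene lists was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. Values outside the central 95% describe these arrays and are not tests of the conditions. Comparisons that share the Hmhi EGF array were set beside 20 simulations of unchanged arrays with the technical spread. Shares have exact (Clopper-Pearson) 95% intervals over genes, which are not replicates.

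The named genes were the 12 with the largest positive and the 12 with the largest negative difference in each comparison with the Hmhi EGF array, and 6 and 6 in the comparison of MYC-TA with Miz1 kd. They had to be at least 2-fold apart, past the level filter and of the same sign in every probe set that passed. RIKEN, Gm and similar models were counted but not named. Zbtb17 (which encodes Miz-1), Myc and Cth were named in every array, and each list contributed up to 4 members with the largest differences. These rules, the lists and the alternatives were fixed before the data were examined.

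The alternatives were a shift to a common median, quantile normalization, a loess correction with span 0.4, no level filter, a filter at the 75th percentile, the mean of all probe sets and only sets ending in a plain _at. The steps were tested on simulated data for the Miz1 kd comparison over 18193 genes. Of genes changed by log2 1.0, 51.0% were recovered at the 2-fold threshold, against 98.2% at log2 1.5 and 99.2% at log2 2. At most 5 false calls were made in any of 10 runs. The simulated spread was only that between probe sets of a gene. Differences between cultures, RNA samples and hybridizations were not simulated, so these rates do not give the false calls in the real comparisons. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.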

Results

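Gene expression was profiled in 4 cultures of mouse melan-a melanocytes, each on 1 array after 14 days. Hmhi cells were starved, or starved with 100 ng/ml EGF. Hmhi-Miz1 kd cells and Hmhi-MYC-TA cells also received EGF. The series title names Myc, Miz-1, melanocyte senescence and cystathionase. There were no replicates, so each difference below compares 2 arrays and not the conditions, and none was tested. All levels are log2 signals, and each array had a median of 6.66. The starved array correlated with the 3 EGF arrays at r of 0.971, 0.968 and 0.971 across probe sets. Hmhi EGF correlated with the array labelled Miz1 kd at 0.9896 and with the MYC-TA array at 0.988. The array labelled Miz1 kd and the MYC-TA array correlated with each other at 0.972, close to the values with the starved array.

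Zbtb17, the gene of Miz-1, was not lower in the array labelled Miz1 kd. Its brighter probe set read 8.73 in Hmhi starved, 8.72 in Hmhi EGF, 9.08 in the array labelled Miz1 kd and 8.71 in MYC-TA. The dimmer set read 6.50, 6.51, 6.72 and 6.78 in that order. Against Hmhi EGF the array labelled Miz1 kd was thus higher by 0.35 and 0.22. The transcript of the target gene does not bear out the label, and these arrays do not measure Miz-1 protein. Directions for this array are therefore those of the array as labelled. Myc, on 1 probe set, read 10.64, 10.60, 10.79 and 9.78, a log2 difference of -0.82 for MYC-TA minus Hmhi EGF. The labels do not spell out MYC-TA, so whether that set also reads a transcript of the construct is not known. Cth, which encodes cystathionase, read 4.343, 5.183, 6.202 and 8.305. It was 8.71-fold higher in MYC-TA than in Hmhi EGF, and 15.6-fold higher than in Hmhi starved. Its first 3 levels were below the array median, where background limits the size of a fold.

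**Figure D1:**
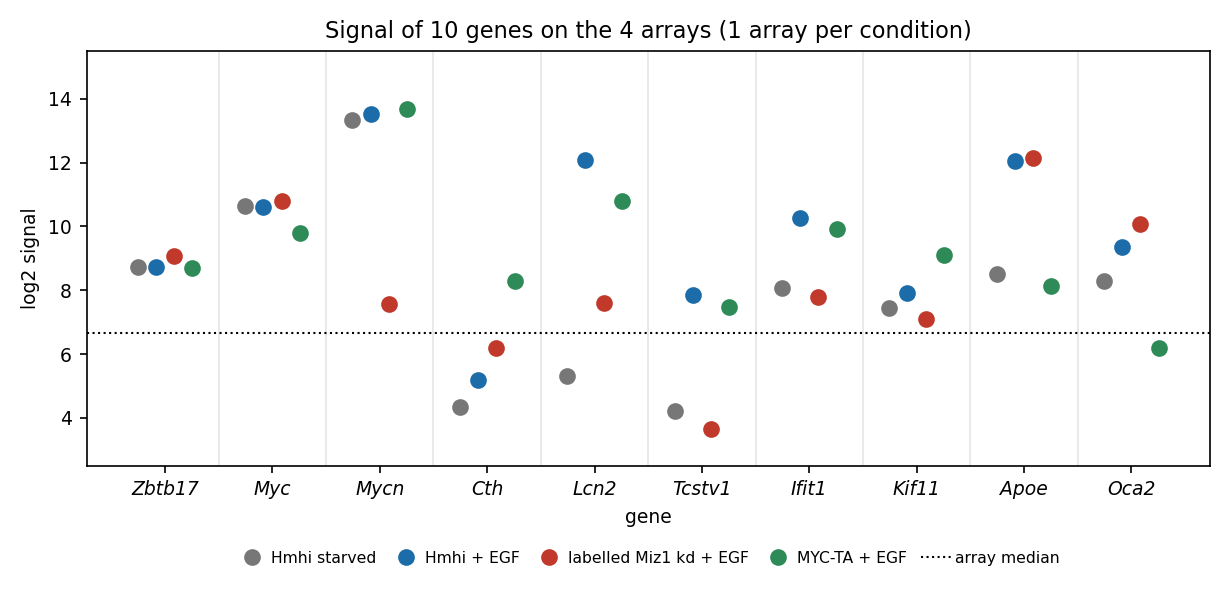
Log2 signal (vertical axis) of 10 genes (horizontal axis), with 1 point per array and the array median as a dotted line. Mycn is at 7.57 in the array labelled Miz1 kd and above 13 in the other arrays, and Cth is above the median only in MYC-TA.

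The comparison of Hmhi EGF with Hmhi starved addresses what 14 days of EGF did to gene expression. Lcn2, Sned1, Wfdc18, Rapgef3 and Adam12 were far higher with EGF, as were Ltbp1, Csn3 and Ptgfrn. Elobl, Panx3, Crygs, Scn7a, Cnn1, Ankrd1, Wt1 and Fos were far lower. Lcn2 went from 5.33 to 12.08. Sned1 went from 6.04 to 11.81, Wfdc18 from 8.27 to 13.39 and Rapgef3 from 6.41 to 11.15. Spsb4, Sorcs2, Gzmd and Cyria were higher by 4.71, 4.66, 4.27 and 4.17. Gzmd belongs to a family of similar genes, so its probe sets are uncertain. Elobl had the largest difference, from 14.47 to 6.76 on 1 probe set. Cnn1 went from 11.72 to 7.93, Fos from 13.94 to 10.58 and Ankrd1 from 8.04 to 4.44. Scel, Fgf13, Kcna1 and Lrtm2 had log2 differences of -3.81, -3.53, -3.38 and -3.31. Of 11461 genes, 915 were at least 2-fold higher and 568 at least 2-fold lower. Lcn2, Sned1, Rapgef3, Spsb4, Adam12, Gzmd, Csn3, Ptgfrn and Cyria read below the array median in Hmhi starved, and Panx3, Crygs, Scel, Ankrd1, Wt1 and Lrtm2 in Hmhi EGF, so background limits the size of these differences and their order.

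Interferon-response genes were higher with EGF, with a list median of 1.08 and 21 of 37 genes at least 2-fold higher. Bst2, Tap1, Usp18 and Rsad2 led them at 3.26, 3.11, 3.08 and 2.99. Mitotic genes had a median of 0.95, with Ccnb2 higher by 1.54 and Mki67 by 1.53. The S-phase list had a median of 0.56, led by Prim1 at 1.95. Pigment cell genes had a median of 0.50, with Apoe higher by 3.53 and Bcan by 3.44, while Rab32 was at -2.30. Lysosomal genes had a median of 0.58, genes of the ATF4 response 0.47 and nuclear envelope and chromatin proteins 0.58. Extracellular matrix genes had a median of 0.44, senescence-associated secreted factors 0.41 and glycolysis genes 0.34, the last of which turned to -0.15 with the filter at the 75th percentile. The list of p53 targets had a median of -0.31, although Cdkn1a was higher by 2.17 and Btg2 was at -2.37. Fibroblast markers had a median of -0.55. These 12 of 22 lists lay outside the central 95% of random lists, against 1.1 expected if genes were independent, which they are not. Receptor tyrosine kinase and ERK feedback genes, with a median of 0.12 inside that range, went both ways, with Etv5 higher by 3.10 and Dusp1 and Egr2 at -2.89 and -3.26. The transsulfuration list was also inside it, at -0.23. The secreted factor, glycolysis, p53 and fibroblast lists came inside it under at least 1 alternative.

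The array labelled Miz1 kd was compared with Hmhi EGF to ask what the knockdown construct changed under EGF. Mycn, Bpifb9b, Lcn2, Cpxm2, Ptgfrn and Masp1 were far lower in it. Tcim, Elobl, Tfcp2l1, Wnt10a and Aqp5 were higher, by smaller amounts. Since Zbtb17 was not lower, these directions belong to the array as labelled. Mycn went from 13.53 to 7.57, which is 62.2-fold, while it read 13.32 in Hmhi starved and 13.68 in MYC-TA. Bpifb9b went from 10.67 to 5.69 and Lcn2 from 12.08 to 7.60. Cpxm2, Ptgfrn and Masp1 had log2 differences of -4.35, -4.31 and -4.27. Usp17la, Tcstv1 and Pramel18 were at -4.22, -4.21 and -3.73, and belong to gene families whose probes can be shared. Cytl1, Col2a1 and Fads2 were at -4, -3.84 and -3.69. Tcim was higher by 2.48, Elobl by 1.95, Tfcp2l1 by 1.75, Wnt10a by 1.67 and Aqp5 by 1.56. Glipr1, Jakmip3, Akr1b8, Kitl and Il11 were higher by 1.42, 1.29, 1.26, 1.26 and 1.23. Hspb8 and Ovgp1 were higher by 1.21 and 1.20. Of 11394 genes, 33 were at least 2-fold higher and 285 at least 2-fold lower. Of the 285, 112 (39.3%) read below the array median in the array labelled Miz1 kd, where background limits the size and order of differences. All the lower genes named here except Mycn and Lcn2 were among them, and Glipr1 and Il11 read below it in Hmhi EGF.

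Interferon-response genes were lower in the array labelled Miz1 kd, with a median of -0.92 and 16 of 37 at least 2-fold lower. The interferon medians with EGF, here and in MYC-TA all use the Hmhi EGF array, so part of each may come from that array. The comparison without it, MYC-TA minus Miz1 kd, had an interferon median of 0.29. Ifit1 and Psmb9 were both at -2.46 and Rtp4 at -1.88. Cholesterol biosynthesis genes had a median of -0.52, with Tm7sf2 at -1.69, Insig1 at -1.17, Idi1 at -1.15 and Hmgcs1 at -1.06. Mitotic genes had a median of -0.23, with Ube2c at -0.94, and S-phase genes -0.13, with Rrm2 at -1.09. The fibroblast list had a median of -0.29, whose sign depended on the probe sets and filter used. Small positive medians were seen for the ATF4 response at 0.19, ribosome biogenesis and MYC-activated genes at 0.16, and receptor tyrosine kinase and ERK feedback genes at 0.13, the last of which turned to -0.054 with the filter at the 75th percentile. Pigment cell genes had a median of 0.054 but a mean of -0.25, since 6 of 33 were at least 2-fold lower. Bcan, Rragd, Dct and St3gal6 were among those, at -2.19, -2.17, -2.07 and -2.03. Genes repressed by MYC through Miz-1 or bound by Miz-1 had a median of 0.088, inside the range of random lists, and the transsulfuration list was inside it at -0.059. In all, 8 of 22 lists lay outside, of which the fibroblast, MYC-activated and receptor tyrosine kinase lists came inside under at least 1 alternative.

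**Figure D2:**
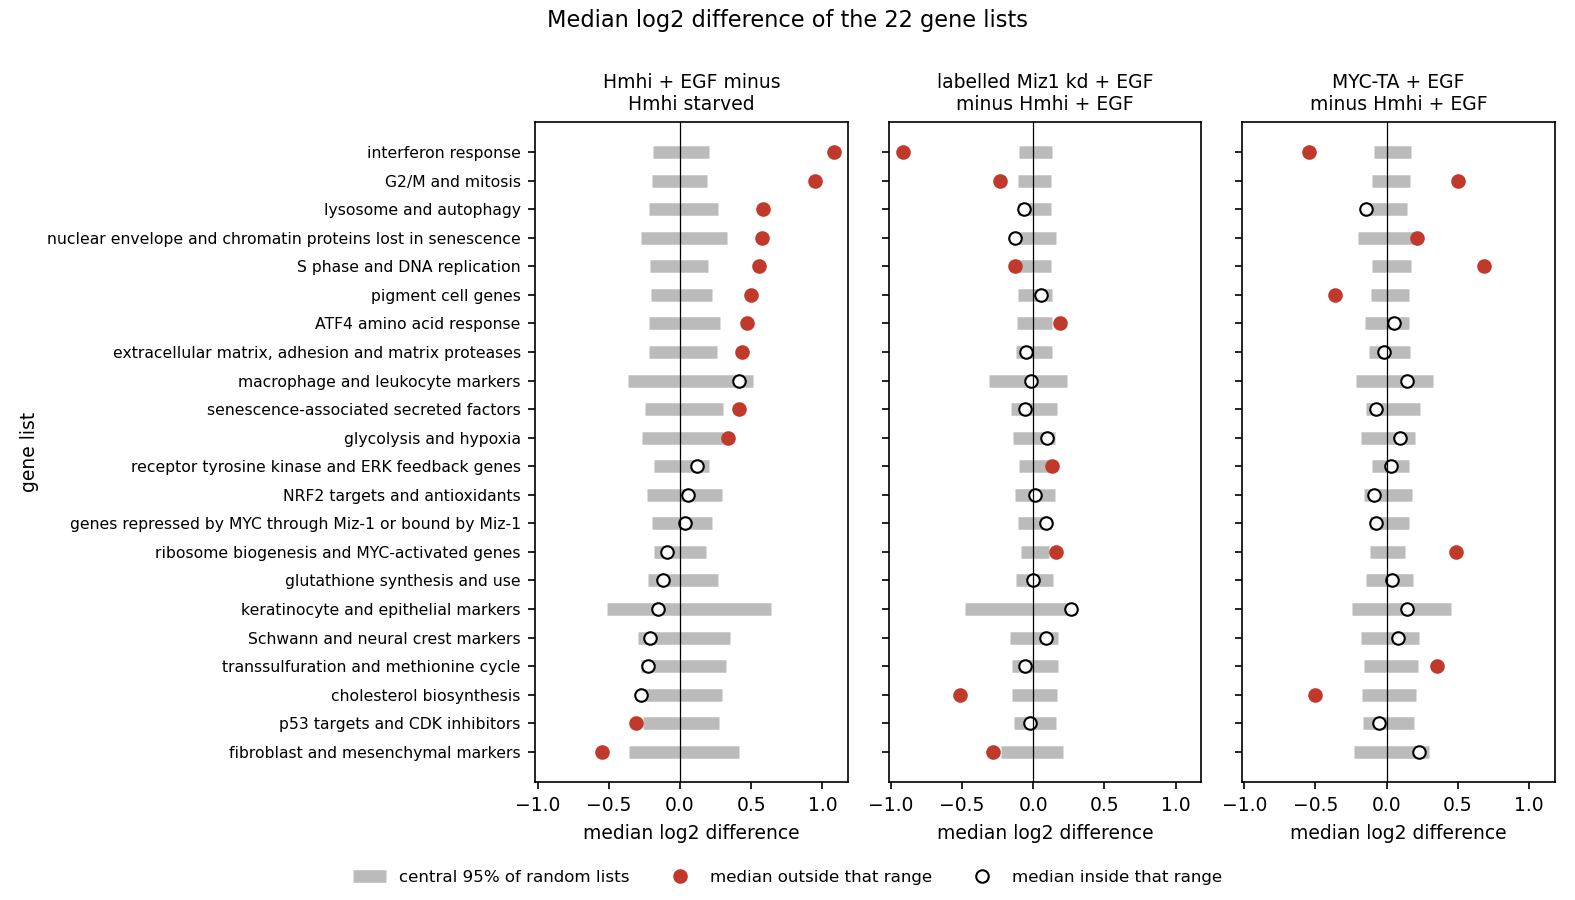
Median log2 difference (horizontal axis) of the 22 gene lists (vertical axis) in the 3 comparisons, with grey bars for the central 95% of random lists and filled points for medians outside them. The interferon list is at 1.08 with EGF, at -0.92 in the array labelled Miz1 kd and at -0.54 in MYC-TA. All 3 comparisons use the Hmhi EGF array, so part of this pattern may come from it.

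MYC-TA with EGF was compared with Hmhi EGF to ask what MYC-TA changed under EGF. An exchange of labels with the array labelled Miz1 kd stays open, so directions for MYC-TA are also those of the array as labelled. Cth, Fetub, Ankrd1, Smpdl3b, S100a6, Ddx4 and Fut9 were among the genes with the largest positive differences. Clca3a2, Apoe, Abca8a, Pdgfrb, Oca2 and Prkag3 had the most negative differences. Cth was higher by 3.12, Fetub by 3.01, Ankrd1 by 2.93, Smpdl3b by 2.91 and S100a6 by 2.85. In Hmhi EGF, Cth, Fetub, Ankrd1, S100a6 and Fut9 read below the array median, at 5.18, 5.71, 4.44, 4.12 and 5.19, so background limits these differences and their order. The same holds for Oca2, Prkag3 and Wnt10a, which read below it in MYC-TA. Ddx4, Fut9, Col3a1, Mgp, Acta2, Igfbp2 and Slc38a1 were higher by 2.72, 2.72, 2.48, 2.30, 2.11, 2.09 and 1.95. Mgp reached 14.58, and Acta2, at 11.80, stood where it had been in Hmhi starved, at 11.81. Clca3a2 went from 11.62 to 7.36, Apoe from 12.05 to 8.13, Abca8a from 10.92 to 7.56 and Pdgfrb from 10.18 to 6.91. Oca2 and Slc45a2, which are pigmentation genes, had log2 differences of -3.16 and -2.70. Prkag3, Wnt10a, Islr, Adgb, Gbp8 and Ccl6 were at -3.15, -2.90, -2.73, -2.72, -2.72 and -2.33. Of 11534 genes, 150 were at least 2-fold higher and 190 at least 2-fold lower.

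S-phase genes were higher in MYC-TA, with a median of 0.69, as were mitotic genes, at 0.50. Mcm5, Mcm3, Cdc6 and Kif11 were higher by 1.10, 1.09, 1.02 and 1.20. Ribosome biogenesis and MYC-activated genes had a median of 0.49 with 5 of 49 at least 2-fold higher, led by Dkc1, Nolc1, Nop58 and Nhp2 at 1.18, 1.12, 1.10 and 1.10. The transsulfuration and methionine list had a median of 0.35, with Tst higher by 1.06 and Mtrr by 0.95 besides Cth. Nuclear envelope and chromatin proteins had a median of 0.22, with Hells, Hmgb2 and Lmnb1 higher by 1.32, 1.08 and 1.02. Interferon genes had a median of -0.54, with Ddx60 at -1.87 and Trim30a at -1.73. Cholesterol genes had a median of -0.50, with Msmo1 at -0.96, and pigment cell genes -0.37. Glutathione genes were inside the range of random lists at 0.038. Genes repressed by MYC through Miz-1 or bound by Miz-1 were also inside it, at -0.076. That list joins repressed and bound genes, so its median here and in the array labelled Miz1 kd does not speak to repression alone. In all, 8 of 22 lists lay outside, of which the transsulfuration and nuclear envelope lists came inside under at least 1 alternative.

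MYC-TA and the array labelled Miz1 kd were also set against each other, both with EGF. Mycn was 69.0-fold higher in MYC-TA, and Igfbp2, Masp1, Ms4a4d, Nfe2l3 and Afap1l2 were higher by 5.18, 5.12, 5.09, 4.94 and 4.93. Wnt10a, Clca3a2, Prkag3, Pdgfrb, Apoe and Oca2 were lower, at -4.57, -4.39, -4.31, -4.26, -4.03 and -3.88. Background limits the size and order of many of these, since the 5 genes after Mycn read below the array median in the array labelled Miz1 kd, and Wnt10a, Prkag3 and Oca2 in MYC-TA. Of 11613 genes, 780 were at least 2-fold higher in MYC-TA and 495 at least 2-fold lower. S-phase genes had a median of 0.83, mitotic genes 0.69 and fibroblast markers 0.78, the last of which turned to -0.24 with only plain _at probe sets. The MYC-activated list had 0.35, nuclear envelope proteins 0.34 and interferon genes 0.29. Pigment cell genes had a median of -0.39 but went both ways, with 6 of 34 at least 2-fold higher and 6 at least 2-fold lower. In all, 7 of 22 lists lay outside. Bacterial poly-A controls also differed between these arrays, by a median of 0.413. The Zbtb17 level does not bear out the Miz1 kd label, so these directions too are those of the arrays as labelled.

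Genes that differed from Hmhi EGF in both arrays went mostly opposite ways. Wnt10a, Prkag3 and Hspb8 were higher in the array labelled Miz1 kd and lower in MYC-TA, and Igfbp2, Mgp, Smpdl3b and Fads2 the reverse. Lcn2, Sned1, Trim30a and Igf2 were lower in both, and Cth, Tcim, Glipr1, Msln and S100a6 higher in both. Cth and S100a6 read below the array median in both Hmhi EGF and the array labelled Miz1 kd, so background limits that difference. They failed the level filter of that comparison and entered here only through their MYC-TA level. Igf2 and Msln were chosen after their values were seen. Genes were counted here if any of the 3 EGF arrays passed the level filter. That gave 301 genes lower and 35 higher in the array labelled Miz1 kd, against 285 and 33 in its own comparison. In numbers, 48 genes were 2-fold apart in opposite directions and 25 in the same direction. Of the 25, 20 were lower in both, against 4.98 for independent lists, and simulated unchanged arrays gave at most 1. Both differences use the Hmhi EGF array, so independence does not hold, and the simulation held technical spread only. A deviation of that culture or RNA sample could also give genes lower in both, so neither number excludes it. The 41 genes lower in the array labelled Miz1 kd and higher in MYC-TA compare with 3.87 for independent lists. Across 11663 genes the differences correlated at r of -0.24, with a Spearman rho of -0.31. Unchanged arrays sharing the Hmhi EGF array gave a simulated r of 0.503. The covariance was -0.0456 against 0.0248 simulated. Genes are not independent replicates.

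**Figure D3:**
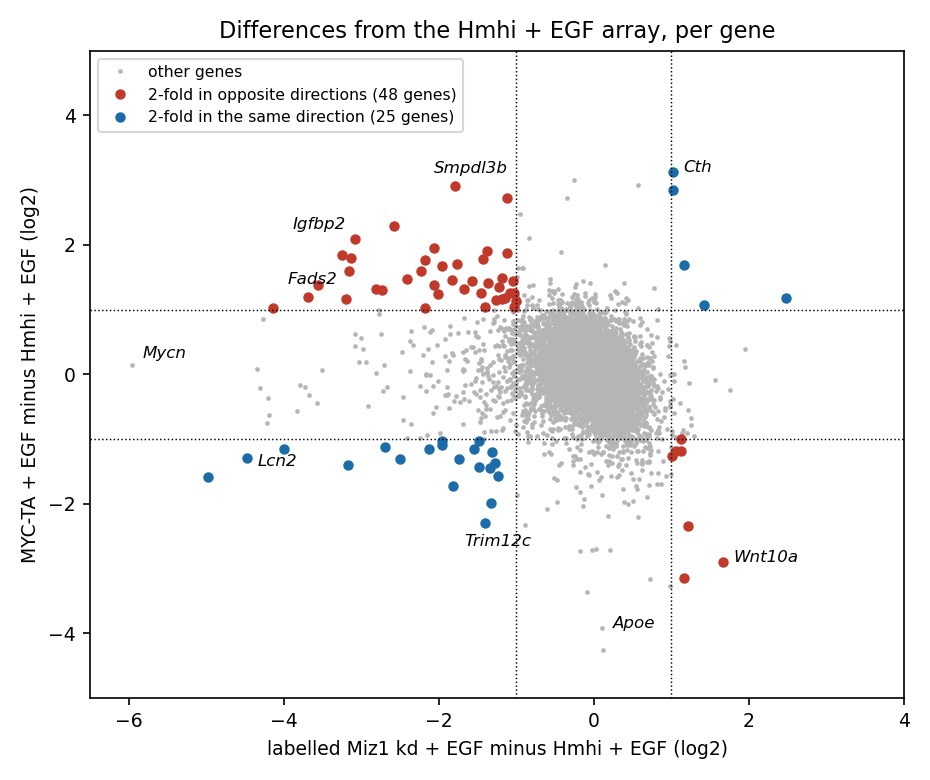
Log2 difference from Hmhi EGF per gene in the array labelled Miz1 kd (horizontal axis) and in MYC-TA (vertical axis), with genes 2-fold apart in both in colour and dotted lines at 2-fold. The 48 genes with opposite directions lie in the upper left and lower right, and the 25 with the same direction in the other corners.

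Part of the EGF difference was absent in the other EGF arrays. Lcn2, higher with EGF, was lower again in both. Tcstv1 and Ptgfrn read about as low in the array labelled Miz1 kd as in Hmhi starved. Both genes were below the array median in these arrays, where background limits any likeness of levels. Acta2, lower with EGF, was back at that level in MYC-TA, and Ddx4, also lower with EGF, read 9.66 there against 9.17 in Hmhi starved. Of the 1483 genes 2-fold apart between Hmhi EGF and Hmhi starved, 220 were at least 50% of the log2 way back in the array labelled Miz1 kd (14.8%, interval 13.1% to 16.7%). In MYC-TA 222 were (14.97%, interval 13.2% to 16.9%). In the array labelled Miz1 kd these were 22.5% of the genes higher with EGF but 2.46% of those lower with it. For MYC-TA the shares were 18.5% and 9.33%. Unchanged arrays gave 0.937% and 0.918% in simulations, which hold technical spread only. The low share of 2.46% is favoured by the few genes higher in the array labelled Miz1 kd. Among genes with any EGF array past the level filter, 35 were 2-fold higher there and 301 lower. Of the 301, 152 were 2-fold higher with EGF, against 23.8 for independent lists. Of the 35, 8 were 2-fold lower with EGF, against 1.51. Both differences use the Hmhi EGF array with opposite signs, so independence does not hold.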

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

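Both results below were looked for after the controls had been seen, and neither explanation nor test was planned for them. The 3 control probe sets of 18S rRNA, which no comparison uses, were higher in Hmhi EGF than in Hmhi starved by a median of 0.833 on the log2 scale. The 3 control sets of murine B1 and B2 repeats were higher by a median of 0.392, with all 3 in that direction. They stand out because they are signals outside the gene comparisons with every set higher and a median above the technical SD between probe sets of 0.32, which does not hold the spread between RNA samples. The lowest repeat set, at 0.248, was below that SD. The 18S sets also differed between the array labelled Miz1 kd and Hmhi EGF, with a median of -0.308 and all 3 lower, and between MYC-TA and Hmhi EGF, with a median of -0.209 and all 3 lower. No cause was tested, and with 1 array per condition EGF and the handling of that RNA sample are confounded.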

How the results depend on the processing

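Every alternative here was chosen before the data were examined. No paired analysis was possible because each condition had 1 array, and for the same reason no array could be left out. The pseudocount alternative was not run, since the values are on a log scale. Under a common median, quantile normalization and loess, all 35 list medians outside the random range stayed outside with their direction. The first 2 settings move little, as the arrays were already normalized. That number was 27 with no level filter, 32 with the filter at the 75th percentile, 31 with the mean of all probe sets and 29 with only plain _at sets. Of the 35 list medians, counted per list and comparison, 25 stayed outside with their direction under every alternative and 10 did not. With EGF these 10 were the secreted factor, glycolysis, p53 and fibroblast lists. In the array labelled Miz1 kd they were the fibroblast, MYC-activated and receptor tyrosine kinase lists. In MYC-TA they were the transsulfuration list (0.16 with no filter and 0.21 with the mean of all sets) and the nuclear envelope list, and for MYC-TA minus Miz1 kd the fibroblast list. Among the 416 named gene values, none that was at least 2-fold in the main setting reversed where a value could be had. Smaller values were not checked for a reversal. The ranked genes had been chosen for the same sign in every probe set that passed, which favours this result under the probe set alternatives. Of the 416 values, 108 moved beyond the technical SD with the mean of all probe sets and 21 with only plain _at sets. With the filter at the 75th percentile, which tests fewer genes, the array labelled Miz1 kd had 19 genes higher and 142 lower. MYC-TA had 92 higher, and 491 were higher in MYC-TA than in the array labelled Miz1 kd. The share back in the array labelled Miz1 kd was 11.7%, and the correlations were -0.28 between the Miz1 kd and MYC-TA differences and -0.086 between the EGF difference and MYC-TA minus Miz1 kd (main value -0.053). The mean of all probe sets left 93 genes higher in MYC-TA. The first correlation was -0.18 with no filter and -0.26 with only plain _at sets, and the second was -0.079 with only plain _at sets. The fibroblast median for the array labelled Miz1 kd reversed to 0.032 with no filter, 0.20 with the mean of all sets and 0.12 with only plain _at sets. For MYC-TA minus Miz1 kd it reversed to -0.24 with only plain _at sets. At the 75th percentile the glycolysis median with EGF reversed to -0.15, and the receptor tyrosine kinase and ERK median in the array labelled Miz1 kd to -0.054. Apart from the smaller gene number at the 75th percentile, the cause was not tested. Signal over background limits the dim genes: in the Miz1 kd comparison the SD between probe sets was 0.30 for the dimmest 20% of probe sets and 0.16 for the brightest 20%.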

Other observations

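Of the tests below, those of the loess correction and of genes bright in the Hmhi EGF array, for the excess of lower genes, were set before their results were seen. The versions by the mean and by the brighter of both arrays were not in the test as written. The others, on the opposite arrays, on Zbtb17 and on the 2 further gene groups, were chosen after the result was seen.

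The Hmhi EGF array lay between the other EGF arrays for 91.1% of the 1278 genes at least 2-fold apart between MYC-TA and the array labelled Miz1 kd. Choosing genes by the gap between the outer arrays favours this, but the same choice put the array labelled Miz1 kd between the others for 21.3% of 343 genes and MYC-TA for 39.0% of 336. A bias of weak signals is argued against, since the correlation of the differences was -0.27 among 6925 genes above the 75th percentile of signal and -0.20 among dimmer ones. An equal mixture of the other RNAs as the Hmhi EGF sample is argued against by 25 genes 2-fold outside both. Simulated equal mixtures, with technical spread only, gave 0. Interferon medians below 0 in both arrays also go against it. Unequal mixtures and a partial carry-over of those RNAs were not simulated. A labelling or RNA input difference cannot be told apart, since bacterial poly-A controls differed by a median of 0.413 between the outer arrays and 24 of 27 sets had Hmhi EGF in between. Opposite effects of the 2 constructs, or of separately derived cell populations, may also underlie it and were not tested.

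Zbtb17 was not lower in the array labelled Miz1 kd. Whether the probe sets fail to report the knockdown cannot be told apart, since they differed by 0.135, less than the technical SD of 0.22, and no other measurement of Zbtb17 is held. An exchange of labels with MYC-TA would lower Zbtb17 there only if the probe sets report the knockdown. MYC-TA differed from Hmhi EGF by -0.014 on the brighter set and 0.273 on the dimmer one, which leaves an exchange open. Neither array was lower than Hmhi EGF beyond the technical SD on either set. An exchange alone would therefore not account for the missing loss of Zbtb17. A loss of the knockdown by day 14 could give the same values and was not tested.

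The array labelled Miz1 kd had 285 genes 2-fold lower and 33 higher. A biological reduction by the construct stays open and was not tested. An intensity-dependent shift of most genes is argued against, since the ratio of lower to higher genes was 13.0 after loess. Loess corrects only such a shift, on arrays already made comparable, so it cannot decide on a bias limited to some genes. Weaker labelling of weak transcripts cannot be told apart. Among genes above the 75th percentile of the Hmhi EGF array, the test as written, the ratio was 10.9 (interval 6.19 to 21.0), past the bound of 4 set for excluding it, but choosing genes by that array alone favours those lower in the other. It was 7.47 (4.61 to 12.8) by the brighter of both arrays and 5.13 (2.98 to 9.38) by their mean, and the last interval reaches below 4. Bacterial poly-A controls were lower in the array labelled Miz1 kd in 26 of 27 sets, by a median of -0.225. This cannot tell weaker labelling from a difference in RNA input. The controls were also lower in Hmhi EGF than in Hmhi starved, in 24 of 27 sets by a median of -0.121, although more genes were higher than lower there.

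Several genes known from the 2-cell embryo were higher with EGF and about as low in the array labelled Miz1 kd as in Hmhi starved. Among them were Tcstv1 (4.22, 7.86 and 3.65 in Hmhi starved, Hmhi EGF and the array labelled Miz1 kd) and Zfp352 (6.42, 8.39 and 6.22). Their low readings were below the array median, where background limits any likeness of levels. A coordinated change of this class may underlie the pattern and was left open. Of 25 measured members, 13 passed the level filter of the EGF comparison, with medians of 2.16 with EGF and -2.75 in the array labelled Miz1 kd. Every member at least 2-fold higher with EGF read below the array median in Hmhi starved, and so passed only through Hmhi EGF. Dim members without such a rise were left out, which by itself favours both medians. The list was also drawn up because its leading genes had been noticed. The Hmhi EGF array alone does not make the pattern, since the median was 3.13 for MYC-TA minus Miz1 kd, and Tcstv1 and Zfp352 read 7.48 and 8.13 in MYC-TA. Without the members among the 30 most changed genes, 7 remained, with medians of 0.388 and -0.208 inside the range of random lists. As the change itself decided which genes were left out, those medians exclude nothing. Of the 7, Zfp352, Arg2 and Sp110 were higher with EGF by 1.96, 2.16 and 1.66 and were at -2.17, -2.75 and -1.46 in the array labelled Miz1 kd, while Tcl1b1, Tcl1b3, Tcl1b4 and Zfp809 were less than 2-fold apart in both. Several of the families have near-identical copies whose probes can be shared. A version shortened after the values of its members were seen lay outside the range, through that selection, and is not used.

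Actin and serum response factor targets may form a group lower with EGF and higher in MYC-TA, which was left open. The list of 19 genes was drawn up after the ranking had been seen, with Cnn1, Ankrd1, Acta2 and Ccn1 in it. Without the most changed genes 11 remained past the filter, with medians of -0.355 with EGF and 0.63 in MYC-TA, both outside the random range (-0.33 to 0.43 and -0.23 to 0.28). Both differences use the Hmhi EGF array with opposite signs, so part of the pattern may come from that array. The 15 genes past the filter before the removal had a median of 0.089 in the array labelled Miz1 kd, inside the range. For MYC-TA minus Miz1 kd the median was 0.12, inside the range, after the removal, and 0.61, outside it, for the 15 genes. As the removal went by size of change, the first of these excludes nothing, and the second holds the genes that prompted the list. Of the 11, Actg2, Flna, Vcl and Ccn2 were higher with EGF, by 0.68, 0.66, 0.53 and 0.16, and Tagln, Flna and Vcl were not higher in MYC-TA, at -0.69, -0.21 and -0.02. A longer list, extended with immediate early genes already seen to be lower, gave -0.37 and 0.36 and is not independent evidence.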
